A study of Mus musculus with 6 samples.

How the data were processed

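Bulk RNA-seq libraries were made from cells of mouse Achilles tendon that carried a tdT reporter of the Tppp3 lineage and had been sorted for it. Per the labels' protocols, tendons came from 3 male mice aged 12 weeks, and the cells were kept for 24 h either in medium with 1% FBS or in medium conditioned by cultures of dorsal root ganglia (DRG), the clusters of sensory neurons beside the spinal cord. The ganglia came from 3 male mice aged 12 weeks and were cultured for 4 to 5 days with antimitotic drugs at 20 µM, after which the medium was changed to one with 1% FBS, collected daily and passed through a 0.22 µm filter. Each of the 2 groups had 3 libraries, which the submitters call biological replicates. The labels do not tie a library to an animal, so the p-values measure the spread between these libraries, part of which may be technical.

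The deposited table holds FPKM values (fragments per kilobase of gene, scaled to the total fragments of a library) that the authors computed for 24413 genes in 6 libraries. The submitters' processing notes name CASAVA, HISAT2 2.0.5 and the mm10 genome build, without stating a role for each. The program that counted fragments, the annotation release, the strand setting and any filter are not given in the sources used here. A few gene symbols of the table (23) had been turned into calendar dates, and 22 table entries shared a symbol with another, of which the entry with the higher mean kept the plain symbol. No column of values was left unused. Of the gene IDs, 24403 were found in the GENCODE annotation of the mm10 assembly, which supplied the coordinates, exon lengths and GC content.

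Within a gene, the FPKM values were whole multiples of what 1 fragment is worth, within a tolerance of 0.01 fragment for 24413 of the 24413 genes. Whole fragments per gene were therefore recovered, and gave a depth of 18599170 to 25825027 fragments per library. The recovered fragments were used for the depth, for floors and for an added alternative, never for the main test. A count of 0 allows up to 3 fragments, and such floors cover counting error only. The total by which the authors had divided exceeded the fragments in the table by 0.93% to 1.99% of that total. Chi-square tests of fragments between libraries of a group gave 3.12 to 6.98 per degree of freedom, so no library was a copy of another.

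The main test was fixed before the data were examined for both a table of counts and a table of FPKM values, and the FPKM version applied. Values were transformed as log2(FPKM + 1), and 11678 genes with a mean of at least 1 FPKM over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (empirical Bayes moderated linear model with a mean-variance trend and robust prior, two-sided, no covariate). Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. A fold change is on the log2(FPKM + 1) scale, which understates changes of low genes. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

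The script functions were tested on simulated data before use: fragments for the 11678 genes were drawn from the real means, library sizes and spread, with 200 genes changed by known folds, in 20 draws. With a spread of its own for each gene, 22.9% of genes changed 1.25-fold, 66.0% of those changed 1.5-fold and 84.2% of those changed 2-fold were recovered, and 6.5% of the calls were false. With a spread shared by genes of like level the recovered shares were 39.7%, 82.2% and 91.5%, and 5.9% of the calls were false. With no gene changed, at most 3 genes and 0 lists were called in a draw by limma at the adjusted threshold. Genes were drawn independently of each other, so these draws cannot show how often lists of genes that vary together are called. A rise of 1.18-fold in the cholesterol synthesis list was called in 20 of 20 draws, with another list called in 1. Every member was given this fold, which is close to the list's mean log2 fold change in the real data (0.235). The draws therefore give no separate evidence for the real call of that list.

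Gene lists were fixed before the data were examined (46 lists) and tested with limma's camera, which asks whether members moved more than other genes. The test used a preset correlation of 0.01, two-sided, for lists with at least 5 tested members (38 lists), with Benjamini-Hochberg adjustment over the lists. An estimated correlation, the self-contained test fry and camera on ranks were alternatives. The lists on tendon and matrix covered tendon fate, tendon sheath progenitors, collagen and matrix, and matrix proteases. Signalling lists covered TGF-beta/SMAD targets, TGF-beta and BMP components, BMP targets, YAP/TAZ targets, p53 targets, the interferon response, NF-kB inflammatory genes, IL-6/STAT3 targets, immediate early genes, MAPK feedback genes, the Wnt pathway, hedgehog and Notch targets, glucocorticoid targets and serum response genes. Lists on nerve signals covered neurotrophins and receptors, neuropeptide ligands and receptors, and axon guidance. Lists on cell state covered contractile genes, proliferation, cartilage and bone genes, and adipogenic genes. Lists on metabolism, stress and housekeeping covered cholesterol synthesis, fatty acid synthesis, hypoxia and glycolysis, the ATF4 stress response, the unfolded protein response, NRF2 targets, metallothioneins, heat shock genes, lysosome and autophagy, cytosolic ribosome, ribosome biogenesis, nuclear oxidative phosphorylation, and mitochondrially encoded genes. Marker lists covered DRG neurons, glia, macrophages, other leukocytes, endothelium, pericytes and smooth muscle, skeletal muscle and erythroid cells.

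Genes are named by a rule also fixed before the data were examined. It takes the 12 largest rises and 12 largest falls among named genes past the threshold with a mean of at least 5 FPKM and no overlap between the groups. It adds up to 4 members with the smallest p in each list described, and always a few genes, among them Tppp3, Scx, Pdgfra and Tgfb1 to Tgfb3. Some genes that the rule takes are not reported here. Alternatives, changed 1 at a time, concerned the scaling (median centring, quantile normalization, TMM factors with 30% trimmed from each side), the low filter (none, or a mean of at least 5 FPKM) and the pseudocount (0.1). Others concerned the variance model, the thresholds (0.01 and 0.10, or an absolute log2 fold change of at least 1), a replicate block and each library left out in turn. Voom on the recovered fragments and removal of a length and GC trend (loess, span 0.5) were added after seeing the data. Alternatives planned for deposited counts were not run.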

Results

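RNA-seq of sorted Tppp3-lineage tendon cells compared 3 libraries kept for 24 h in DRG conditioned medium with 3 libraries kept in 1% FBS medium. The recovered depth was 21552683, 18599170 and 23241077 fragments in conditioned replicates 1, 2 and 3. It was 22946924, 25825027 and 19768489 fragments in control replicates 1, 2 and 3. The comparison addresses what medium conditioned by sensory ganglion cultures does to gene expression in these cells. Factors released by the ganglia cannot be told apart from use of the medium by the cultures or residue of the antimitotic drugs. Values are FPKM as mean ± SD with n = 3 per group unless stated otherwise, and log2 fold changes are conditioned minus control with their standard error (SE).

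Conditioned medium raised all 30 tested genes of the interferon response list (camera adjusted p = 1.5e-55) and lowered 14 of 23 tested genes of the tendon fate list (camera adjusted p = 1.5e-14). Ifit3, an interferon-induced antiviral protein, rose from 15.1 ± 0.849 to 91.0 ± 3.11 FPKM, and Isg15, a ubiquitin-like interferon-induced modifier, rose from 29.6 ± 4.61 to 145 ± 13.8 FPKM. Nov, a secreted matricellular protein, fell from 43.8 ± 1.53 to 19.4 ± 0.643 FPKM, and Col1a1, the main chain of type I collagen, fell from 3336.5 ± 35.8 to 2662 ± 38.3 FPKM. Of 24 sterol synthesis genes, 15 rose by smaller amounts and 9 did not pass (camera adjusted p = 1.3e-15). Of 11678 genes tested, 472 were higher and 291 lower with conditioned medium at an adjusted p below 0.05 in limma (763 genes, 6.53%), and 43 of the higher and 3 of the lower genes had an absolute log2 fold change of at least 1. The groups did not overlap for 3032 genes (26.0%), against 10% by chance. The 6 libraries separated by medium on the first principal component, which held 39.8% of the variance. Pearson correlations of log2 values across genes, which are not independent replicates, ran from 0.990 to 0.992 within groups and from 0.984 to 0.988 between groups.

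**Figure D1:**
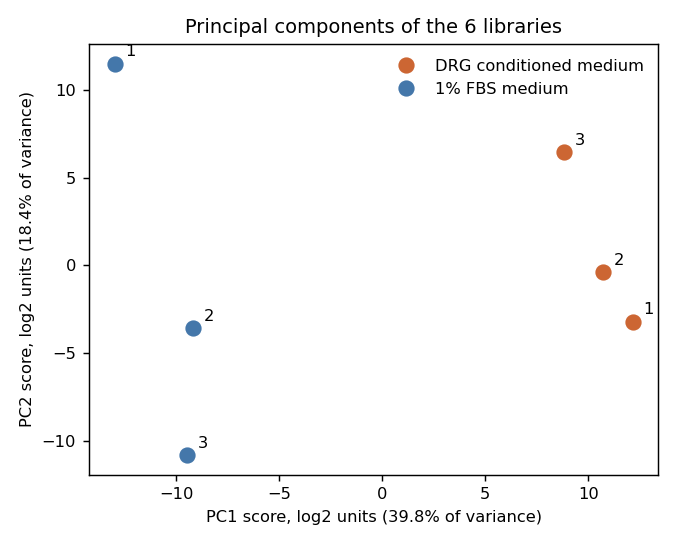
Scores of the 6 libraries on the first 2 principal components of log2(FPKM + 1) over the 11678 genes tested, in log2 units, with each point a library, numbers giving the replicate and colours giving the medium. The first component (39.8% of variance) has all 3 conditioned libraries on one side and all 3 control libraries on the other.

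The changes described first are those of named genes with a mean of at least 5 FPKM and no overlap between the groups. Among the 12 largest rises, 10 belonged to the interferon response list. Prl2c3, a gene of the prolactin family, had the largest log2 fold change, 2.77 ± 0.12 SE (from 4.35 ± 0.930 to 35.1 ± 1.05 FPKM, adjusted p = 4.6e-05), and its near-identical neighbour Prl2c2 rose by 2.39 ± 0.10 SE. Fragments may be split between those genes by the authors' counting, so the value of each is uncertain. Prl2c3 lies on chromosome 13 from 12790816 to 12800079 and Prl2c2 from 12996125 to 13005383 (mm10). Nov (chromosome 15 from 54745702 to 54754039) had the largest fall of these genes, with a log2 fold change of -1.14 ± 0.04 SE and an adjusted p of 3.7e-06. Other falls within the same limits were those of Piezo2, a mechanically gated ion channel (-0.96), Sema3c, a secreted axon guidance protein (-0.85), Igfbp2, an IGF-binding protein (-0.84), Cxcl14, a chemokine (-0.79), and H19, an imprinted noncoding RNA (-0.75). Lgr5, a receptor for R-spondins, Col8a2, Itm2a, Fbn2, Cthrc1 and Lrrc17 fell by 0.73, 0.72, 0.70, 0.67, 0.64 and 0.63.

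**Figure D2:**
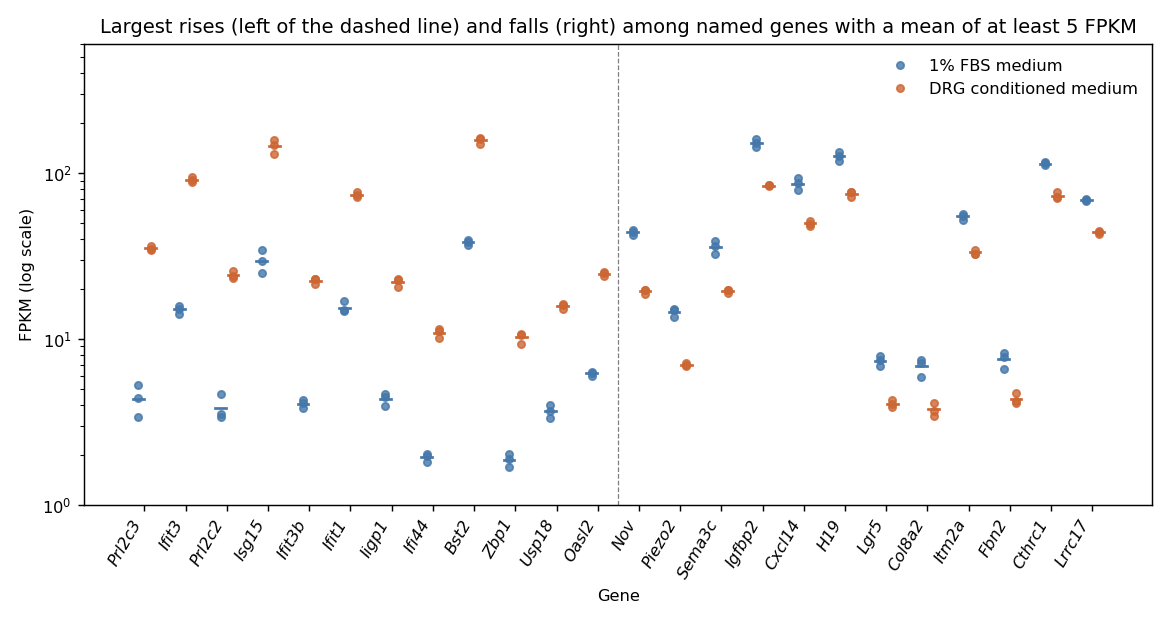
FPKM per library (log scale) of the 12 largest rises and 12 largest falls among named genes with a mean of at least 5 FPKM and no overlap between groups, with points for libraries, short lines for group means and colours for the medium. Ifit3 went from a mean of 15.1 to 91.0 FPKM and Nov from 43.8 to 19.4 FPKM, and the groups do not overlap for any gene shown.

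All 30 tested members of the interferon response list rose (30 also when adjusted over the list alone, camera adjusted p = 1.5e-55), and the call held with an estimated correlation (adjusted p = 0.0051). The list median was 1.31. Of 40 genes listed, 39 were in the deposited data, and those with a mean below 1 FPKM were not tested. That mean covers both groups, so a low gene that rises passes the filter more easily. Among the untested members, Cxcl10 had 84 fragments in control and 90 in conditioned libraries, while Psmb9 had 142 and 264. Ifit3, Ifit3b and Ifit1, neighbours on chromosome 19, rose by 2.52 ± 0.05 SE, 2.21 ± 0.05 SE and 2.19 ± 0.06 SE. Bst2, which tethers budding virus, went from 38.3 ± 1.47 to 158 ± 6.91 FPKM, and Oasl2, a protein related to oligoadenylate synthetases, from 6.19 ± 0.190 to 24.7 ± 0.680 FPKM. Iigp1, Ifi44, Zbp1 and Usp18 rose by 2.11, 2.02, 1.97 and 1.84.

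Of 23 tested tendon fate genes, 14 fell, 0 rose and 9 did not pass (16 lower and 1 higher adjusted over the list alone, camera adjusted p = 1.5e-14), and this call too held with an estimated correlation (adjusted p = 0.023). Col14a1, a fibril-associated collagen, went from 41.1 ± 2.26 to 26.7 ± 0.558 FPKM, Fmod, a collagen-binding proteoglycan, from 140 ± 3.37 to 102 ± 4.33 FPKM, and Postn, a matricellular protein, from 135 ± 1.14 to 101 ± 1.95 FPKM. Scx, the tendon transcription factor, had 13.2 ± 0.551 FPKM in control and 11.5 ± 0.433 FPKM in conditioned medium and did not pass (adjusted p = 0.073). Collagen and matrix genes had 10 lower, 2 higher and 22 not passing of 34 (11 lower and 6 higher adjusted over the list alone, camera adjusted p = 6.9e-04, adjusted p = 0.13 with an estimated correlation). Col1a2, Sparc and Fbln5 fell by 0.36, 0.28 and 0.32. The collagen and matrix list shares members with the tendon fate list, Col1a1 and Col1a2 among them, so the falls of these lists are not separate results. Matrix proteases and their inhibitors had 5 lower, 2 higher and 13 not passing of 20 (9 lower and 3 higher adjusted over the list alone, camera adjusted p = 0.010, adjusted p = 0.11 with an estimated correlation). The bone-resorbing protease Ctsk, Adamts1 and Plat fell by 0.35, 0.23 and 0.27.

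Of the 24 cholesterol synthesis genes, 15 rose, 0 fell and 9 did not pass (21 higher adjusted over the list alone, camera adjusted p = 1.3e-15, adjusted p = 0.014 with an estimated correlation). The sterol enzymes Msmo1, Lss and Mvd rose by 0.36, 0.35 and 0.40, with Msmo1 going from 24.1 ± 0.705 to 31.2 ± 0.952 FPKM. Fatty acid synthesis had 6 higher and 8 not passing of 14 (11 higher adjusted over the list alone, camera adjusted p = 3.7e-08, adjusted p = 0.098 with an estimated correlation). Acly rose by 0.26 and kept its call in all 17 settings with the thresholds unchanged. Fasn, Scd1 and Fads1 had log2 fold changes of 0.22, 0.21 and 0.16 and lost theirs in 5, 5 and 7 settings, with Fads1 down to 0.10. NRF2 targets had 9 higher and 7 not passing of 16 (10 higher adjusted over the list alone, camera adjusted p = 3.9e-10, adjusted p = 0.079 with an estimated correlation). Nqo1, a quinone reductase, went from 16.0 ± 1.09 to 36.6 ± 1.51 FPKM, Gstm1, a glutathione transferase, from 70.5 ± 2.39 to 117 ± 3.49 FPKM, and Gclm and Hmox1 rose by 0.42 and 0.49. Hypoxia and glycolysis genes had 4 higher and 21 not passing of 25 (7 higher adjusted over the list alone, camera adjusted p = 2.0e-04, adjusted p = 0.098 with an estimated correlation). Pkm, Vegfa, Aldoa and Adm rose by 0.36, 0.26, 0.20 and 0.19.

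Contractile genes had 8 higher and 12 not passing of 20 (11 higher and 1 lower adjusted over the list alone, camera adjusted p = 7.0e-07, adjusted p = 0.066 with an estimated correlation). Lmod1, Vcl, Myh11 and Myh9 rose by 0.60, 0.39, 0.31 and 0.24. Proliferation genes had 6 higher and 38 not passing of 44 (17 higher adjusted over the list alone, camera adjusted p = 6.9e-07, adjusted p = 0.079 with an estimated correlation). Ccnb2, Kif20a, Plk1 and Tpx2 rose by 0.46, 0.36, 0.32 and 0.27. YAP/TAZ targets had 3 higher and 14 not passing of 17 (7 higher adjusted over the list alone, camera adjusted p = 1.5e-04, adjusted p = 0.098 with an estimated correlation). Ankrd1 went from 42.1 ± 1.21 to 66.6 ± 0.746 FPKM. Serum response genes had 4 higher, 1 lower and 12 not passing of 17 (4 and 1 adjusted over the list alone, camera adjusted p = 0.0052, adjusted p = 0.098 with an estimated correlation). Actb rose by 0.26 (0.17 with quantile normalization) and Egr3 fell by 0.79. IL-6/STAT3 targets had 3 higher, 1 lower and 9 not passing of 13 (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0011, adjusted p = 0.20 with an estimated correlation). Socs3, Bcl3 and Cebpd rose by 0.65, 0.42 and 0.32. Heat shock genes had 2 higher, Hspa1b (0.58), kept in all 17 settings, and Hspd1 (0.15), lost in 10 with a value down to 0.09, and 13 not passing of 15 (6 higher adjusted over the list alone, camera adjusted p = 0.0010, adjusted p = 0.098 with an estimated correlation). Lysosome and autophagy genes had 5 higher and 15 not passing of 20 (6 higher adjusted over the list alone, camera adjusted p = 0.0028, adjusted p = 0.21 with an estimated correlation). Ctsb and Grn rose by 0.25 and 0.20. Cytosolic ribosome genes had 1 higher, Rps18 (0.28), and 32 not passing of 33 (1 higher adjusted over the list alone, camera adjusted p = 5.0e-07, adjusted p = 0.32 with an estimated correlation).

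MAPK feedback genes had 2 lower, Spry1 (-0.56) and Dusp5 (-0.45), and 16 not passing of 18 (9 lower adjusted over the list alone, camera adjusted p = 4.1e-05, adjusted p = 0.066 with an estimated correlation). Immediate early genes had 6 lower, 1 higher and 14 not passing of 21 (11 lower and 2 higher adjusted over the list alone, camera adjusted p = 8.7e-04, adjusted p = 0.29 with an estimated correlation). Nr4a1 and Egr2 fell by 0.53 and 0.43, and Fosl2 rose by 0.40. Axon guidance genes had 5 lower, 1 higher and 20 not passing of 26 (8 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.0011, adjusted p = 0.24 with an estimated correlation). Sema7a and Sema3d had log2 fold changes of -0.44 and -0.43 alongside the fall of Sema3c, and Ntn4 rose by 0.28. The Wnt pathway had 4 lower, 1 higher and 18 not passing of 23 (5 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0095, adjusted p = 0.21 with an estimated correlation). Its call was lost by camera on ranks, where the adjusted p was 0.055, the highest among the settings with the preset correlation. Dkk2, Wnt2 and Rspo3 had log2 fold changes of -0.34, -0.49 and -0.31. Hedgehog and Notch targets had 2 lower, Hes1 (-0.40) and Jag1 (-0.33), and 7 not passing of 9 (4 lower adjusted over the list alone, camera adjusted p = 0.0027, adjusted p = 0.21 with an estimated correlation). The p53 targets had 3 lower, Plk2, Plk3 and Sesn2 (-0.22, -0.37 and -0.21), and 25 not passing of 28 (6 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0031, adjusted p = 0.098 with an estimated correlation). Of 12 mitochondrially encoded genes 0 passed in limma (0 adjusted over the list alone, 1 at an unadjusted p below 0.05, 1 by voom). Their median log2 fold change was -0.15 (camera adjusted p = 0.019, adjusted p = 0.44 with an estimated correlation). The call was lost without control replicate 1 or conditioned replicate 1, with no low filter, and with the length and GC trend removed (highest adjusted p = 0.18).

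**Figure D3:**
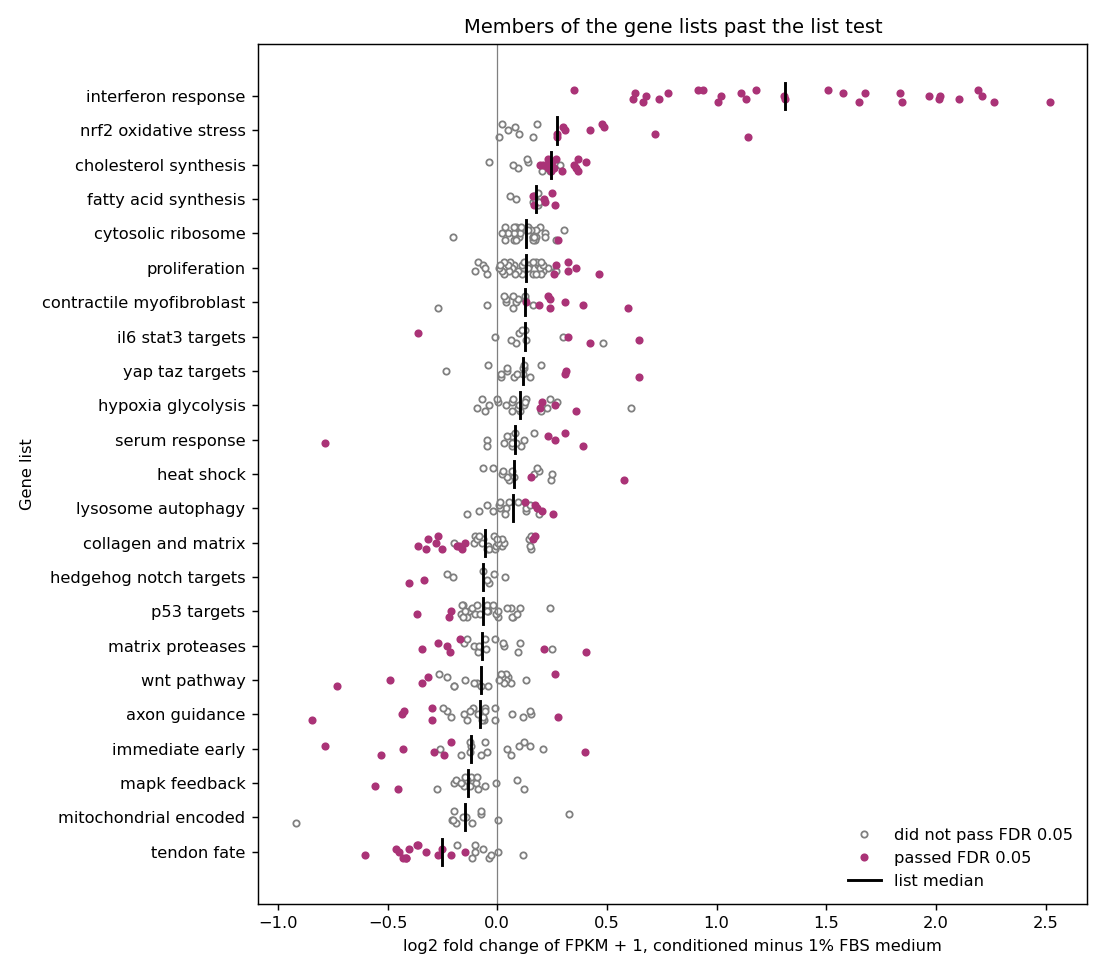
Log2 fold changes of FPKM + 1 (conditioned minus control) of the members of the 23 lists past the list test, with filled points for members that passed at an adjusted p of 0.05, open points for those that did not, and a bar at each list's median. The interferon response list stands apart with a median of 1.31, and the tendon fate list has the lowest median, -0.25.

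The remaining lists tested did not pass. TGF-beta and BMP components had 3 higher, 5 lower and 25 not passing of 33 (5 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.18). Grem1, a secreted BMP antagonist, went from 4.69 ± 0.275 to 9.92 ± 0.566 FPKM, Tgfbr3 rose by 0.44, and Fst and Tgfbr2 fell by 0.41 and 0.32. Tgfb1, Tgfb2 and Tgfb3 had log2 fold changes of -0.19, -0.07 and 0.05 (adjusted p = 0.074, 0.58 and 0.41). TGF-beta/SMAD targets had 1 higher, 4 lower and 27 not passing of 32 (2 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.35). Cdkn2b and Klf10 had log2 fold changes of -0.29 and -0.37. BMP targets had 1 higher, Grem1, of 9 (1 adjusted over the list alone, camera adjusted p = 0.27). Tendon sheath progenitor genes had 2 higher, 4 lower and 9 not passing of 15 (3 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.44, median 0.0033 against a mean of -0.05). Ly6a, an interferon-responsive surface protein, went from 448 ± 13.6 to 617 ± 7.30 FPKM, and Cd34 fell from 5.71 ± 0.0261 to 3.84 ± 0.260 FPKM. Cilp and Pi16 had log2 fold changes of -0.19 and -0.34. Pdgfra had 34.0 ± 1.67 and 38.3 ± 0.179 FPKM and did not pass (adjusted p = 0.062). Tppp3 itself lay below the level filter, with 0.724 to 1.05 FPKM in control and 0.777 to 1.12 FPKM in conditioned libraries (27 to 51 fragments).

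Neurotrophins and receptors had 2 higher, 3 lower and 7 not passing of 12 (2 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.51, median 0.05 against a mean of -0.0024). Gfra1, a GDNF receptor, had a log2 fold change of 0.41. Ptn and Lif fell by 0.35 and 0.36. Neuropeptide ligands and receptors had 2 higher, Adra2a (0.53) and Adm (0.19), and 5 not passing of 7 (2 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.85). NF-kB inflammatory genes had 5 higher, 1 lower and 14 not passing of 20 (6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.18, median -0.01 against a mean of 0.07). The chemokine Ccl2 went from 46.5 ± 2.80 to 66.7 ± 1.13 FPKM, and Cxcl5, Ccl7 and Csf1 rose by 0.44, 0.40 and 0.23. Glucocorticoid targets had 4 higher, 1 lower and 6 not passing of 11 (4 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.32, median -0.02 against a mean of 0.15). Angptl4, a lipase inhibitor, went from 3.91 ± 0.564 to 9.63 ± 0.259 FPKM. Cartilage and bone genes had 2 higher, 1 lower and 4 not passing of 7 (2 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.71, downward with a median of -0.13 against a mean of 0.0071). Spp1, osteopontin, went from 68.3 ± 3.71 to 118 ± 2.46 FPKM, Sox9 rose by 0.32 and Col2a1 fell by 0.50. Adipogenic genes had 2 higher, Lpl (0.67) and Cebpa (0.44), and 3 not passing of 5 (2 adjusted over the list alone, camera adjusted p = 0.28). The ATF4 stress response had 1 lower, Sesn2, of 23 (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.43). The unfolded protein response, ribosome biogenesis and nuclear oxidative phosphorylation had 0 passing of 20, 25 and 31 in limma (0 adjusted over each list alone, camera adjusted p = 0.061, 0.89 and 0.20). At an unadjusted p below 0.05 these had 4, 2 and 5 genes, and by voom 1, 0 and 0. The metallothionein list had 3 tested genes, too few for a list test, of which Mt1 was the only metallothionein and rose by 0.46. The zinc transporters Slc39a10 and Slc30a1 had log2 fold changes of -0.21 and -0.10 and did not pass. Adjusted over the list alone, 1 was higher and 1 lower (median -0.10 against a mean of 0.05).

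Markers of other cell types were mostly below the level filter. Of 25 DRG neuron markers 3 were tested, and of these Tubb3, a tubulin, fell from 22.6 ± 1.20 to 16.5 ± 0.653 FPKM (1 lower adjusted over the list alone, median 0.0016 against a mean of -0.06). Glia and macrophage lists had 3 tested markers each with 0 passing in limma (1 lower in each adjusted over the list alone, 1 in each at an unadjusted p below 0.05, 0 by voom), among them S100b with 2.42 ± 0.173 and 1.50 ± 0.522 FPKM and Lyz2 with 2.68 ± 0.457 and 1.79 ± 0.301 FPKM. The median of the macrophage markers was 0.12 against a mean of -0.05. Other leukocyte and erythroid markers had 0 tested. Of 2 tested endothelial markers Tek fell, from 5.90 ± 0.377 to 4.50 ± 0.301 FPKM (1 adjusted over the list alone), and of 4 skeletal muscle markers 0 passed in limma (1 lower adjusted over the list alone, 1 at an unadjusted p below 0.05, 0 by voom). Pericyte and smooth muscle markers had 1 higher, Myh11, and 6 not passing of 7 (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.98, upward with a median of 0.01 against a mean of -0.02).

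Fewer genes passed whichever library was left out, and each such fit has fewer samples. A dependence on individual libraries therefore cannot be told apart from the smaller sample. Without control replicates 1, 2 and 3 in turn, the higher genes numbered 426, 310 and 402 and the lower genes 252, 152 and 205. Without conditioned replicates 1, 2 and 3 in turn, the higher genes numbered 274, 265 and 364 and the lower genes 138, 129 and 170. Of the 23 lists past the test, 3 held with an estimated correlation, namely interferon response, cholesterol synthesis and tendon fate. Among the genes named above, calls of Adm, Cebpa, Klf10, Cilp, Plk3, Tpx2, Vegfa, Tek, Sema7a, Gfra1, Sema3d, Rspo3, Rps18, Aldoa and Sesn2 were also lost in 5 to 8 settings, the fits without 1 library among them.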

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

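Voom on recovered fragments and the removal of a length and GC trend were chosen only after the data were seen. With 472 genes higher and 291 lower as the values reported, the number of higher genes fell to 43 and of lower genes to 3 at an absolute log2 fold change of at least 1, and to 248 and 113 at an adjusted p below 0.01, by construction. The lower genes numbered 165 with no low filter, 443 at an adjusted p below 0.10 and 473 with voom, and the cause of the first and last was not tested. Leaving out each library in turn gave 265 to 426 higher and 129 to 252 lower genes and 22 to 24 lists, with fewer samples in each fit. In the other settings, the replicate block apart, the counts stayed within 1.5 times the values reported, and 0 of the 763 changed genes switched sign in any setting. No pairing by the replicate numbers shared by the groups was visible, as deviations of libraries with the same number correlated at -0.095, -0.008 and -0.048. The labels do not say what a number marks, so a pairing is not excluded. A replicate block gave 259 higher and 131 lower genes and 23 lists. Of the 23 lists, 3 passed with an estimated correlation and 21 with fry, which does not compare a list with other genes and called 28 of all 38. Of 120 named genes past the threshold, 86 passed in every setting and 34 did not in at least 1. Among the named genes that did not pass, 22 passed in at least 1 setting. Genes below a mean of 1 FPKM, Tppp3 among them, were left out by the filter chosen and tested only without it, and the tests and scalings listed beforehand for a table of counts were not run.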

Other observations

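The gene groups of the next 2 paragraphs and every test in this part were chosen only after the result was seen. The median of the LXR targets is the exception, as it was chosen before its value was seen. The groups hold genes already found to change, among them H19, Cxcl14, Tap1 and Psmb8. Their camera p-values therefore describe the genes chosen and are no evidence that a group changed. The adjusted ones were adjusted over the lists added in this part, not over the 38 lists tested above.

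Antigen presentation genes of class I rose along with the interferon response: of 16 tested, 13 were higher, 0 lower and 3 did not pass (camera adjusted p = 7.9e-13, unadjusted p = 0.012 with an estimated correlation). H2-T23 went from 14.1 ± 0.584 to 23.3 ± 0.306 FPKM (SD, n = 3), and B2m from 296 ± 12.6 to 342 ± 11.4 FPKM. Tap1 and Psmb8 belong to this list and to the interferon response list. Among 12 tested chemokines, 6 rose, 1 fell and 5 did not pass (camera adjusted p = 0.0056, unadjusted p = 0.17 with an estimated correlation). Ccl8 went from 7.31 ± 1.38 to 17.4 ± 2.26 FPKM and Ccl9 from 5.55 ± 0.260 to 11.7 ± 0.299 FPKM, while Cxcl14 fell.

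Imprinted genes that are often expressed together had 6 lower, 0 higher and 9 not passing of 15 (camera adjusted p = 8.8e-06, unadjusted p = 0.0080 with an estimated correlation). H19 went from 127 ± 7.72 to 75.1 ± 3.32 FPKM, Mest from 8.71 ± 0.251 to 5.49 ± 0.360 FPKM, Cdkn1c from 10.1 ± 0.698 to 6.83 ± 0.109 FPKM and Meg3 from 41.0 ± 1.71 to 30.5 ± 0.701 FPKM. Plagl1 and Slc22a18 were the other lower members. Grb10 had 52.7 ± 2.72 and 52.7 ± 1.09 FPKM and did not pass.

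The real split of the 6 libraries gave 763 changed genes and 23 lists. Among the 10 possible splits, the real one was the only 1 with as many genes and the only 1 with as many lists, and the highest other split gave 1 gene and 11 lists. With 10 splits a share under 0.05 cannot be reached. Each of the other splits sets 2 libraries of one medium and 1 of the other against the reverse, so it keeps part of the medium difference and gives no value free of it.

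The interferon-stimulated genes rose in all 3 conditioned libraries, and their summed level rose by 625 FPKM. Leukocytes, neurons or glia carried over from the ganglion cultures are argued against, since their summed markers changed by -5.07 ± 0.733 FPKM (SE), or by 1.08 ± 1.35 FPKM without Tubb3, which control cells also express and which carried the fall, and 48 markers below the filter summed to 7.39 FPKM in control and 6.12 FPKM in conditioned libraries. Scaling is argued against too, because the lowest mean log2 fold change of the list over 3 scalings was 1.38. Interferon gamma stays open. The class II genes examined for it, Ciita among them, averaged 1.26 FPKM in conditioned libraries, mostly from H2-DMa and H2-DMb1. H2-DMa had 2.18 FPKM in control and 2.51 FPKM in conditioned libraries, and H2-DMb1 had 2.97 and 3.81 FPKM. Neither passed (limma adjusted p = 0.55 and 0.36). The other class II genes lay below the level filter and showed no common rise. H2-Ab1 had 0.462 FPKM in control and 0.485 FPKM in conditioned libraries, H2-Eb1 had 0.871 and 0.662 FPKM, and Cd74 had 0.131 and 0.0745 FPKM. Ciita had 27 fragments in control and 28 in conditioned libraries, but whether these cells can switch on Ciita was not tested. An interferon or another inducer in the conditioned medium may therefore act on the cells, and which one was not tested.

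Sterol synthesis genes rose by a mean of 0.24 (log2). A lower sterol supply from the conditioned medium was predicted to lower the targets of the oxysterol receptor LXR. The median log2 fold change of 8 tested targets was 0.14 ± 0.07 SE (over genes, not libraries), above 0 by more than its SE, so the predicted fall was not seen. The prediction also named Abca1 and Abcg1 as lower. Abca1 was at 0.11, and Abcg1, below the level filter, had 0.724 FPKM in control and 1.14 FPKM in conditioned libraries. Lpcat3, at 0.20, was the 1 target that passed, and 7 did not pass. Of the 8 targets, 6 had a positive and 2 a negative log2 fold change. Whether LXR was active in these cells was not tested, so a lower sterol supply stays open. A trend with exon length and GC content is argued against, since the mean stayed at 0.24 with that trend removed. A regulatory signal from the medium that acts on these genes by another route is a further candidate explanation and was not tested.

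Xist, the noncoding RNA of the inactive X chromosome, and transcripts of Y-linked genes were found together above 3 fragments in 6 of 6 libraries, although the labels give male mice as the source of tendons. Xist had 19.5 to 26.5 FPKM, and Ddx3y had 2.71 to 3.02 FPKM against 54.5 to 59.5 FPKM for its X-linked partner Ddx3x. Libraries of female cells and libraries of male cells are argued against, as every library held both. Fragments of 4 Y-linked genes made up 6.08% ± 0.330 (SD over the libraries) of those genes and their X-linked partners, and the ratio differed between libraries by up to 1.17 times with a chi-square p of 0.0216, which counts fragments as independent, so pools with slightly different shares of male cells cannot be told apart from spread between libraries. A pool of cells from female and male animals could give this mixture, and the labels' sex was not checked in another way.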
